A study of Homo sapiens with 2 samples.

How the data were processed

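ATAC-seq libraries of the human embryonic stem cell line WIBR3 were compared, 1 from primed cells and 1 from hTBLCs. Per the labels' protocols, living cells were collected and ATAC-seq followed a published protocol with some modification. The submitters' processing notes name Bowtie2, Picard and MACS2 and the build hg38, with no version, role or setting. Whether reads were shifted for the transposase offset, how duplicates and mitochondrial reads were treated and which calling threshold was used are not given in the sources used here. Peaks were called in each library separately, since each sample has its own list, and no replicate was analysed here.

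The authors deposited for each peak a start, an end and a summit offset in bp, a whole-number score, a fold enrichment, a −log10 p and a −log10 q. The deposited score equals 10 times the −log10 p rounded down with a maximum of 1000, and was not used. The fold ratio in the authors' lists is the summit over the local background of the same library, and it was used to rank and describe peaks within a list and to solve for the pileups below, which were compared across the libraries. The −log10 p-value and q-value columns of the authors' lists were used to filter and rank peaks. The lowest deposited −log10 p was 2.00 in the primed and 2.83 in the hTBLC list, whose last rank is 300000, so the lists end at different thresholds. Of the primed peaks, 6362 lay below the lowest hTBLC −log10 p. Ranks without a line numbered 252 in primed and 327 in hTBLC, and a region in such a line counts as absent here.

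For each peak, a whole pileup and a local background were solved from the deposited fold and −log10 p, with fold as the pileup plus 1 over the background plus 1 and p as the Poisson upper tail. Whole pileups were found for 99.999% of the primed and 99.998% of the hTBLC peaks, with a tolerance of 0.001 in −log10 p. The most frequent lowest background, 1.79 and 1.96, was taken as relative depth, and ratios of hTBLC to primed pileups were scaled by it. A ratio is given only where the strongest regions of both libraries overlap, with an exact binomial 95% interval for counting error. Total read numbers were not analysed here, so depth is known only through this background.

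Overlapping or touching peaks of a library were merged into regions on chromosomes 1 to 22 and X, and 16 peaks elsewhere were left out of each list. A region was shared when it overlapped a region of the other library by at least 1 bp. Gene positions came from a RefSeq gene table of assembly GRCh38.p14, which has the primary coordinates of hg38 and gives gene starts and ends without strand, transcripts or exons. Promoters were therefore replaced by gene ends, within 1 kb of either end of a protein-coding gene, so a gene end can be the 3′ end. Transcript starts further inside a gene were not examined. Other classes were the body of any annotated gene and intergenic positions, by the summit of the strongest peak. Reference shares came from positions every 1 kb. Each library-only region was given to the protein-coding gene with the nearest end within 50 kb. Motifs, base composition and repeats need a genome sequence and were not analysed here.

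Comparisons, gene lists, the naming rule and most alternatives were fixed before the data were examined. The rule named the 10 genes per direction of highest fold among gene ends open in 1 library, the 10 genes per direction with the largest difference in nearby library-only regions, the members of each list with a gene end open in 1 library or the largest difference, and 10 genes fixed by name. For olfactory receptor, ZNF and protocadherin genes only a few of the genes the rule selects are named, and some other genes it selects are not reported here. The strongest single regions, the regions of extreme ratio, the extreme windows and the top 5 peaks were chosen after their values were seen.

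No test across conditions was made, since each group has 1 library. Shares have Wilson 95% intervals. Each list's hTBLC-only share was placed among 10000 random lists of the same size, matched gene by gene on decile of library-only regions, as a description of these libraries. The same was done for the mean log2 ratio at shared regions. The alternatives were a −log10 q of at least 5 or 10, the top 50000 regions, reciprocal overlap of at least 50%, shared within 500 bp, scaling to equal depth, gene end windows of 500 and 2500 bp, distances of 10 and 200 kb, leaving out regions at gene ends and leaving out chromosome X. A common −log10 p floor of 2.83, with and without scaling for depth, the gene end of stronger signal alone, gene end regions without contact to the other library, removal of further lines with a fold limit of 10 at gene ends, unscaled ratios and intervals over resampled genes or windows were added after the data were seen. Random lists for alternatives numbered 1000.

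The steps were tested on simulated data. Simulated pileups were recovered for 100% of 20000 peaks in each library's setting. Among lists of 20 genes drawn from 16138 genes with library-only regions, a planted odds ratio of 1.5 for hTBLC-only regions was detected in 60% and an odds ratio of 2 in 100%, and no list of 20 genes passed without a shift. Of lists of 200 genes, 100% passed at both odds ratios and 5% passed without a shift. Each setting had only 20 lists, of genes drawn at random with independent regions, and only the upper tail was checked. The rates therefore do not cover gene families that cluster on chromosomes, or lists below the random range. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.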

Results

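Accessible chromatin was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in the human embryonic stem cell line WIBR3. One library came from primed cells, the conventional state of human embryonic stem cells, and 1 came from hTBLCs, the study's name for totipotent blastomere-like cells obtained by repressing the spliceosome. The study asked which chromatin opened and which closed between these states. The authors' peak lists held 295753 peaks for the primed library and 299673 for the hTBLC library. After overlapping peaks were merged on chromosomes 1 to 22 and X, 242009 primed regions covered 103.5 Mb and 250859 hTBLC regions covered 104.9 Mb, with median widths of 330 bp and 324 bp. The background level behind the calls was 1.79 in the primed library and 1.96 in the hTBLC library. Their ratio of 1.09 was taken as the relative depth, which was not measured from read numbers. The median pileup at a peak summit, the number of reads or fragments stacked there, was 18 in the primed and 17 in the hTBLC library. With 1 library per group there was no replicate spread, and no test across the conditions was possible. Shares carry Wilson 95% intervals and pileups exact Poisson 95% intervals, which cover counting error only. Fold enrichments are the authors' own values for each peak. Coordinates are on hg38.

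The first comparison asked how much of the accessible genome the 2 states had in common. Of the primed regions, 62.7% (62.5 to 62.9) touched an hTBLC region, and of the hTBLC regions 60.8% (60.6 to 61.0) touched a primed region. This left 90203 primed-only and 98291 hTBLC-only regions. The strongest regions were nearly all common to both libraries: in the strongest 10% of each list the shared share was 98.0% for primed and 98.4% for hTBLC, against 31.7% and 27.4% in the weakest 10%. Library-only regions had a median pileup of 12 in both libraries, and shared regions a median of 24. A stricter class, library-only regions with a −log10 q of at least 10, held 13428 primed-only and 11999 hTBLC-only regions. Which library had more library-only regions depended on the threshold: hTBLC-only regions were 52.1% of the total in the full lists and 45.8% when both lists were held to a −log10 q of at least 5.

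By fold enrichment, the strongest primed-only region of all lay inside a gene 76067 bp from the nearest protein-coding gene end, that of VPS41, on chromosome 7 at 38798657 to 38799203, with a pileup of 170 (145 to 198). The strongest hTBLC-only region lay between genes on chromosome 9 at 25742164 to 25742661, with TUSC1 as the nearest gene, 64016 bp away, and a pileup of 105 (85.9 to 127). Another strong hTBLC-only region, with a pileup of 108 (88.6 to 130), lay inside a gene 8298 bp from an end of ITGA2, which encodes an integrin subunit, on chromosome 5 at 52997408 to 52997874. Both peak lists opened with the same 5 sites. The first of them overlaid MTATP6P1, a nuclear copy of mitochondrial DNA on chromosome 1, with pileups of 5082 in primed and 7170 in hTBLC, so reads of mitochondrial origin can contribute there. Ranks without a line in the lists, 252 in primed and 327 in hTBLC, set a limit on single sites. When as many further lines were taken out of the hTBLC list at neighbouring ranks, a median of 16.5 regions of the strongest 10% (range 9 to 23 in 20 draws) became primed-only, against 492 observed.

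The location of the regions relative to genes was compared next. Regions at the ends of protein-coding genes, within 1 kb of either end, were mostly shared: 11.6% (11.4 to 11.7) of the shared primed regions lay there, against 3.73% (3.61 to 3.86) of primed-only and 2.69% (2.59 to 2.80) of hTBLC-only regions. Intergenic positions held 39.8% (39.5 to 40.1) of the hTBLC-only regions and 33.4% (33.1 to 33.7) of the primed-only regions, with 33.5% among shared regions. Gene bodies held 62.8% of the primed-only and 57.5% of the hTBLC-only regions. Of evenly spaced genome positions, 2.39% fell at gene ends and 44.0% were intergenic. Among library-only regions with a −log10 q of at least 10, the intergenic share was 33.2% (32.4 to 34.0) for primed and 38.6% (37.8 to 39.5) for hTBLC. When only the top 50000 regions of each list were used, the order at gene ends turned, with 6.44% of primed-only and 7.50% of hTBLC-only regions there.

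**Figure D1:**
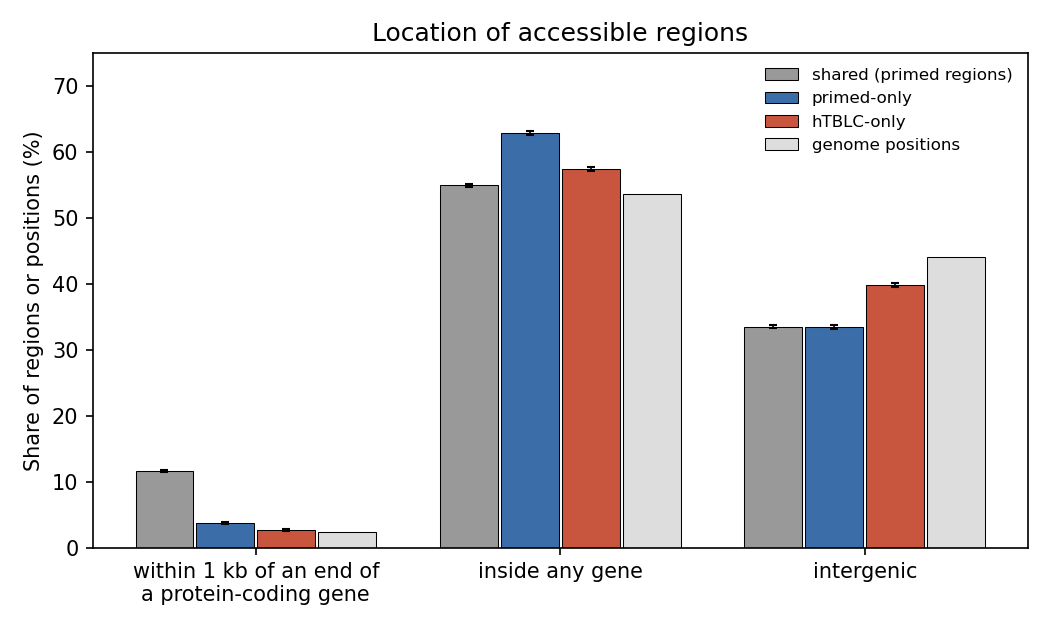
The y axis gives the share (%) of regions or genome positions in each location class, with grey bars for primed regions shared with hTBLC, blue bars for primed-only regions, red bars for hTBLC-only regions and pale bars for evenly spaced genome positions; error bars are Wilson 95% intervals. Shared regions reach 11.6% at gene ends, and hTBLC-only regions reach 39.8% in intergenic positions against 33.4% for primed-only regions.

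At the level of genes, 15693 of 19974 protein-coding genes (78.6%, 78.0 to 79.1) had a region at a gene end in both libraries. A gene end region was present in the primed library alone for 668 genes (3.34%, 3.10 to 3.60) and in the hTBLC library alone for 590 genes (2.95%, 2.73 to 3.20), and 3023 genes had none. Strand and transcripts were not available, so such a region can lie at a 3′ end, and starts further inside a gene were not examined. The 10 primed-only genes of highest fold enrichment were DYNC2I1, CMTM2, WDFY4, ALDH3B1, ZNF671, RBMS2, PGK2, TMPRSS12, NOXRED1 and CALCB. The 10 hTBLC-only genes were OR6A2, GOLGA6D, GTPBP2, OR4S1, AKAP6, FGF1, CIROZ, SPEM1, FCGR3A and USP45. In 5 of these primed and 6 of these hTBLC genes, the region reached the window from outside and touched a region of the other library beyond the 1 kb limit. The genes so affected were CMTM2, WDFY4, ALDH3B1, RBMS2 and CALCB, and OR6A2, GOLGA6D, GTPBP2, FGF1, CIROZ and FCGR3A. Over all genes this held for 41 primed-only and 40 hTBLC-only genes, and 627 and 550 genes had a region confined to 1 list.

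Among the genes without such contact, DYNC2I1, which encodes a subunit of the dynein motor of cilia, had a primed region on chromosome 7 at 158957916 to 158958405 with a pileup of 87 (69.7 to 107). PGK2, a testis-specific phosphoglycerate kinase, had a primed region with a pileup of 50 (37.1 to 65.9), and TMPRSS12 one with a pileup of 51 (38.0 to 67.1). ZNF671, a zinc finger gene on chromosome 19, had a primed region at 57726998 to 57727943 with a pileup of 64 (49.3 to 81.7). Of the hTBLC-only genes, AKAP6, which encodes an anchoring protein of protein kinase A, had a pileup of 54 (40.6 to 70.5), SPEM1 one of 57 (43.2 to 73.9) and USP45, a deubiquitinase gene, one of 38 (26.9 to 52.2). With the top 50000 regions of each list, the counts changed order, to 874 primed-only and 1097 hTBLC-only genes. Of the primed-only gene ends, 57 had a fold enrichment of at least 10, and removing further lines from the hTBLC list made a median of 2 more (range 0 to 6 in 20 draws). For hTBLC-only gene ends these numbers were 17 and 1 (range 0 to 4).

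Library-only regions were then given to the protein-coding gene with the nearest end within 50 kb. Of 93320 such regions, 48.0% were hTBLC-only, and 5993 genes had more hTBLC-only than primed-only regions while 7826 had more primed-only regions. The largest excess of hTBLC-only regions was at ZNF608, a zinc finger gene, with 25 hTBLC-only and 9 primed-only regions. MAGEB10, a cancer-testis antigen gene on chromosome X, had 14 hTBLC-only regions and 0 primed-only. PRTG, which encodes the developmental receptor protogenin, and ST3GAL1, which encodes a sialyltransferase, each had 18 against 5. EDNRB (the endothelin receptor type B gene), GREB1L, SMIM31 and LOC124902135 each had 14 against 1, and BPNT2 and the glutamate receptor gene GRIA2 each had 13 against 0. Of these 10 genes, 6 had overlapping gene end regions in both libraries. The scaled ratio of their pileups lay above 1 at 4 of them, PRTG, GREB1L, ST3GAL1 and BPNT2, and its interval included 1 at ZNF608 and GRIA2. At PRTG the pileup was 48 (35.4 to 63.6) in primed and 177 (152 to 205) in hTBLC, a scaled ratio of 3.37 (2.44 to 4.74), and at GREB1L the ratio was 2.74 (1.82 to 4.23). It was 1.64 (1.32 to 2.03) at BPNT2, 0.89 (0.67 to 1.17) at ZNF608 and 0.99 (0.76 to 1.29) at GRIA2.

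In the other direction, PHF21B had 2 hTBLC-only and 23 primed-only regions, and GCNT2, a gene of blood group I glycan branching, had 8 and 23. RBM47, which encodes an RNA-binding protein, and GRIA3 had 19 primed-only regions each, with 3 and 4 hTBLC-only regions. SPIN1, which encodes a reader of histone methylation, had 16 primed-only and 0 hTBLC-only regions, and TDRP had 14 and 0. NFIB had 18 primed-only and 4 hTBLC-only regions, USP9X 17 and 3, and GPR176 15 and 1. At the shared gene end region the scaled hTBLC to primed ratio was 0.55 (0.35 to 0.84) for RBM47 and 0.61 (0.49 to 0.77) for GRIA3, while USP9X had a ratio of 1.56 (1.23 to 1.99). Among the 9 genes of this group with a ratio, it lay below 1 at 4 and above 1 at 1, and the interval included 1 at 4. Without scaling it lay below 1 at 3, since the interval at TDRP then included 1. The excess changed sign in at least 1 alternative setting for ZNF608, ST3GAL1, GRIA2, NFIB and GPR176. The total within 50 kb, 48.0% hTBLC-only, was 50.2% within 200 kb.

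The lists of genes fixed in advance were examined because the study concerned a change of developmental state. Core pluripotency genes had 49 hTBLC-only and 82 primed-only regions nearby, a share of 37.4% (29.6 to 45.9), which lay at percentile 1.84 of 10000 random gene lists with a median of 48.1%. TERF1, a telomere-binding protein gene, contributed most, with 0 hTBLC-only and 10 primed-only regions, and without it the share was 40.5%, at percentile 8.15, inside the central 95% of random lists. SOX2 had 2 hTBLC-only and 8 primed-only regions. At its shared gene end region on chromosome 3 the pileup was 116 (95.9 to 139) in primed and 85 (67.9 to 105) in hTBLC, a scaled ratio of 0.67 (0.50 to 0.89). NANOG had pileups of 35 (24.4 to 48.7) and 21 (13 to 32.1), a ratio of 0.55 (0.30 to 0.97), or 0.60 (0.33 to 1.06) without scaling, so its separation from 1 rests on the scaling. At SOX2 the ratio without scaling was 0.73 (0.55 to 0.98). Across all gene end regions matched 1 to 1, the scaled log2 ratio had quartiles of −0.39 and 0.30. An interval that excludes 1 covers counting error only and does not set a gene apart from this spread. POU5F1, which encodes the pluripotency factor OCT4, had a gene end region in primed alone, on chromosome 6 at 31170581 to 31170794 with a pileup of 37 (26.1 to 51.0). Its fold enrichment was only 2.94, with a −log10 q of 6.90. The gene had 6 primed-only against 0 hTBLC-only regions nearby. NODAL, LEFTY2 and ZFP42 had a gene end region in hTBLC alone, with pileups of 31, 25 and 10. Their fold enrichments were 6.78, 2.21 and 3.72, and the −log10 q at LEFTY2 was 2.56. Strand was not available, so whether the regions at these genes and at POU5F1 lie at promoters or at 3′ ends was not determined. SALL4 had 6 hTBLC-only and 2 primed-only regions. The list's percentile was 22.3 when only regions within 10 kb were counted and 23.4 with the top 50000 regions of each list.

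Genes of the human 8-cell stage and other totipotency markers lay, as a group, within the central 95% of random lists, with 44 hTBLC-only and 48 primed-only regions (47.8%, 37.9 to 57.9, percentile 59.0). Of 36 such genes, 22 had no gene end region in either library and 10 had one in both. Some of the listed genes belong to families of related genes. How well reads can be placed there was not analysed, so a missing region does not establish closed chromatin. ZSCAN4, a marker of the 8-cell embryo, had a gene end region in primed alone, with a pileup of 15 (8.40 to 24.7), as did the histone variant gene H3Y1 with 18. ARGFX and TRIM49 had one in hTBLC alone, with pileups of 13 and 7. DPPA3 had pileups of 30 (20.2 to 42.8) in primed and 21 (13 to 32.1) in hTBLC, a ratio of 0.64 (0.35 to 1.16), which was not separable from 1 at this depth. Without strand, whether this end of DPPA3 holds its promoter was not determined. KLF17 had gene end regions in both libraries, and the strongest of each, with pileups of 13 and 15, did not overlap each other. The hTBLC region touched another primed region, while the primed one touched no hTBLC region. KHDC1L had 3 hTBLC-only and 0 primed-only regions nearby, and DPRX 0 and 5. The genes CPHX1 and CPHX2 of this list had no protein-coding entry in the gene table.

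The markers of primed and naive pluripotency had shares of 52.3% (44.9 to 59.7) and 52.8% (44.7 to 60.8), both within the central 95% of random lists. The naive share lay below the random median at stricter thresholds, still within that range, with 40.5% at a −log10 q of at least 5 and 31.2% (percentile 5.2) at 10. It was 26.1% (percentile 6.2) among library-only regions with a −log10 q of at least 10 and 37.0% within 10 kb. In the primed list, PTPRZ1 had 12 hTBLC-only and 5 primed-only regions and THY1 had 2 and 9, and CD24 had a gene end region in primed alone with a pileup of 51. In the naive list, PRDM1 had 12 hTBLC-only and 8 primed-only regions and ESRRB 8 and 11, and ALPG and NR5A2 had gene end regions in primed alone with pileups of 9 and 26. At shared regions near the naive genes, the mean log2 ratio of hTBLC to primed pileups was −0.38, at percentile 1.37 of random lists, and near the core pluripotency genes it was −0.31, at percentile 7.12. By this measure 4 of 19 lists lay outside the central 95% of random lists, 2 low and 2 high.

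Among markers of other cell types, trophectoderm genes had a share of 43.1% (36.0 to 50.5, percentile 11.4), with GATA3 at 11 hTBLC-only and 7 primed-only regions and TP63 at 2 and 10. TP63 and ABCG2 had a gene end region in primed alone, with pileups of 20 and 18. GCM1 had one in hTBLC alone, with a pileup of 7, the lowest called in that library, and a −log10 q of 1.46. Without strand, whether these regions lie at promoters or at 3′ ends was not determined. Endoderm genes had a share of 56.7% (48.5 to 64.6, percentile 94.3), with PDGFRA at 6 hTBLC-only and 0 primed-only regions and GATA4 at 7 and 12. HNF4A had a gene end region in hTBLC alone, with a pileup of 11, and GATA6 had 5 hTBLC-only and 3 primed-only regions. The endoderm share was 70% of 20 regions, at percentile 99.1, when only library-only regions with a −log10 q of at least 10 were counted, and its percentile was 97.9 with that threshold on both lists, 99.1 with the top 50000 regions and 99.9 within 200 kb. Neural genes had a share of 40.4% (32.9 to 48.4, percentile 4.48). This depended on the threshold, with 46.0% at percentile 66.9 when both lists were held to a −log10 q of at least 5 and 47.7% at percentile 69.8 at 10. SIX3 had a gene end region in primed alone and FOXD3 had one in hTBLC alone, and SOX3 had 10 hTBLC-only and 6 primed-only regions. Mesoderm genes had a share of 46.6% (37.3 to 56.2, percentile 35.8). SNAI2 had 9 hTBLC-only and 1 primed-only region and GSC 1 and 8, and the gene end region was in hTBLC alone at HAND2 and in primed alone at TBX1. Fibroblast genes had equal numbers, 34 and 34. COL3A1, a collagen gene, had 8 and 3 and POSTN 3 and 1, both with a gene end region in hTBLC alone, and TWIST2 had 4 and 10. At shared regions the mean log2 ratio of the fibroblast genes was 0.08, at percentile 97.3.

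All 24 splicing factor genes had a gene end region in both libraries. At SF3B1, which encodes a core component of the U2 spliceosome, the pileup was 74 (58.1 to 92.9) in primed and 121 (100 to 145) in hTBLC, a scaled ratio of 1.49 (1.11 to 2.02). This ratio was not ranked among those of all shared gene ends. Nearby library-only regions of this list were 16 hTBLC-only and 26 primed-only (38.1%, 25 to 53.2, percentile 14.2), with SF3B3 at 0 and 7 and SNRPB at 3 and 0. Targets of p53 had a share of 53% (43.3 to 62.5, percentile 82.1). CDKN1A, the best known of them, had no gene end region in either list. Transcript starts further inside the gene were not examined, so this does not show that its promoter was closed. ZMAT3 had 9 hTBLC-only and 6 primed-only regions, TP53INP1 2 and 5, and BBC3 had a gene end region in primed alone with a pileup of 7. The AP-1 and stress response genes had equal numbers, 36 and 36, with ATF3 at 12 and 5. At shared regions their mean log2 ratio was −0.40, at percentile 2.44, and at the gene end of FOSL1, an AP-1 subunit gene, the pileup was 105 (85.9 to 127) in primed and 27 (17.8 to 39.3) in hTBLC, a ratio of 0.24 (0.15 to 0.36).

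Genes of DNA methylation had a share of 43.4% (31.0 to 56.7, percentile 28.3), with the demethylase genes TET2 at 6 hTBLC-only and 0 primed-only regions and TET3 at 1 and 9. Housekeeping genes, used as a reference, had 16 and 17, with YWHAZ at 6 and 4 and ACTB at 2 and 4. Of the gene families chosen by symbol, olfactory receptor genes had 254 hTBLC-only and 182 primed-only regions (58.3%, 53.6 to 62.8), above all 10000 random lists. Their gene ends carried a region in hTBLC alone for 31 genes and in primed alone for 13, and 314 of 392 genes had none. OR5AK2 had 7 hTBLC-only and 0 primed-only regions and OR2V1 1 and 4. Their mean log2 ratio at shared regions was −0.10, at percentile 96.2. Protocadherin genes had 6 hTBLC-only and 23 primed-only regions (20.7%, 9.85 to 38.4, percentile 0.605), with 9 gene ends open in primed alone and 0 in hTBLC alone. The strongest of these 9 was at PCDHB16, with a pileup of 28. PCDHB15 had 0 hTBLC-only and 2 primed-only regions and PCDHGC5 2 and 0. At shared regions the mean log2 ratio of this family was −0.43, at percentile 3.56. Genes named ZNF had 502 and 669 (42.9%, 40.1 to 45.7, percentile 0.15), with ZNF236 at 0 and 12 and gene ends open in primed alone for 8 genes and in hTBLC alone for 6. At shared regions the ZNF genes leaned the other way, with a mean log2 ratio of −0.07 against a random median of −0.18, above all random lists. HOX genes had 37 and 64 (36.6%, 27.9 to 46.4, percentile 5.91), with HOXA2 at 3 and 0 and HOXB9 at 2 and 7. Regions at HOXA9, HOXA11 and HOXD12 that lay within 1 kb in 1 library alone touched a region of the other library further out. Histone genes had 21 and 23 (47.7%, 33.8 to 62.1, percentile 78.3). H2AC19 had 2 and 0, H2AC12 1 and 4, and H2BC3 and H4C6 had gene end regions in primed alone. The histone share was 54.5% at percentile 98.8 with a −log10 q of at least 5, 56.4% at percentile 99.1 at 10 and 69.6% of 23 regions at percentile 99.3 with the top 50000. It was 35.7%, at percentile 27.5, with regions within 500 bp counted as shared. At shared regions the histone genes had a mean log2 ratio of 0.09 against a random median of −0.21, at percentile 99.99. By library-only regions, 4 of 19 lists lay outside the central 95% of their random lists, and the members of gene families cluster on chromosomes while the random lists are scattered. The protocadherin percentile was 6.50 with a −log10 q of at least 5, where the share was 21.7% of 23 regions. At 10 it was 9.25, with a share of 20% of 15 regions. The percentile of ZNF genes was 15.5 within 200 kb. With the top 50000 regions the ZNF genes turned, to 1.72 points above the random median at percentile 72, and the percentile of olfactory receptor genes was 91.2.

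**Figure D2:**
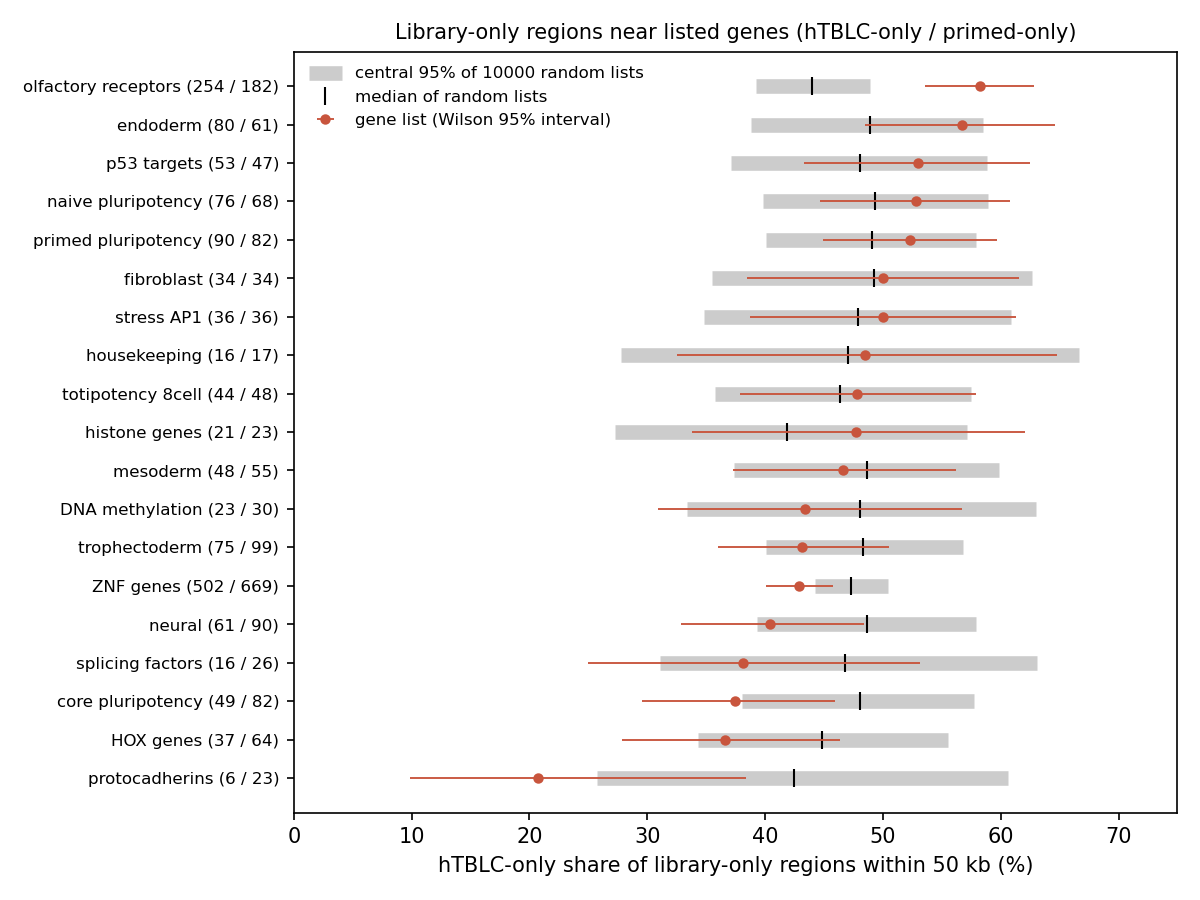
The x axis gives the hTBLC-only share (%) of library-only regions within 50 kb of the genes of each list, with the numbers of hTBLC-only and primed-only regions beside the list names; red points are the lists with Wilson 95% intervals, grey bars the central 95% of 10000 random lists and black marks their medians. Olfactory receptor genes at 58.3% lie above the grey bar, and core pluripotency genes at 37.4%, ZNF genes at 42.9% and protocadherin genes at 20.7% lie below it.

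**Figure D3:**
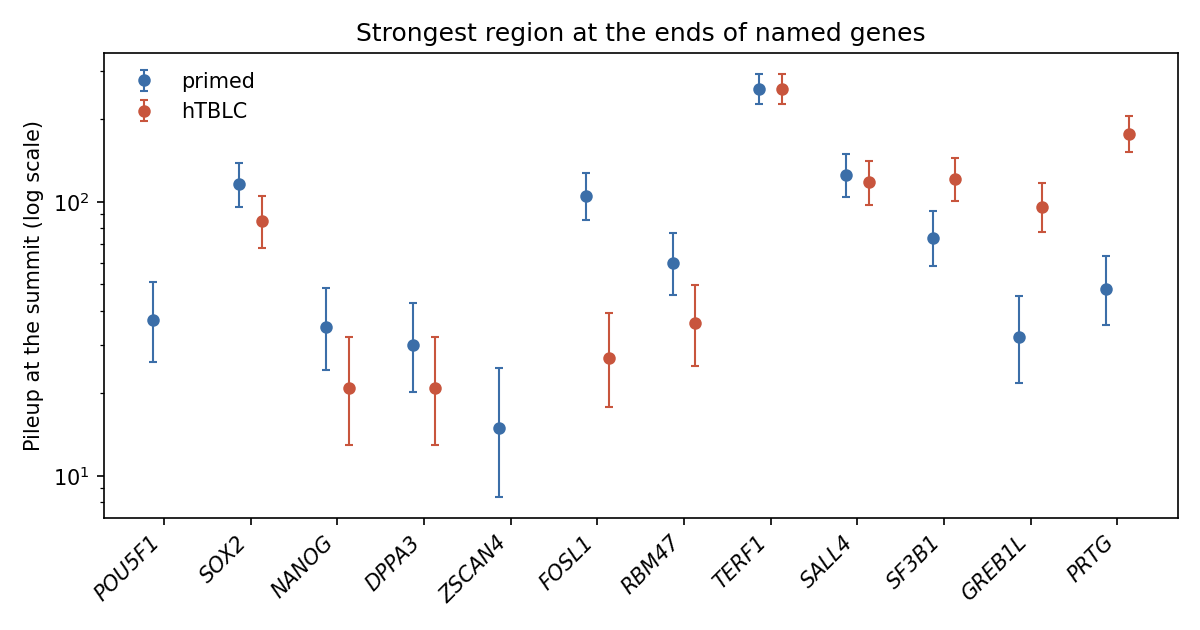
The y axis gives, on a log scale, the pileup at the strongest region within 1 kb of the ends of each named gene, in the primed (blue) and hTBLC (red) library; bars are exact Poisson 95% intervals, and a gene without a point in a library had no region there. POU5F1 and ZSCAN4 have a primed point alone, FOSL1 has 105 in primed and 27 in hTBLC, and PRTG has 48 and 177.

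At 139523 regions that matched 1 to 1 between the libraries, signal strength was compared after scaling by the background level. The median log2 ratio of hTBLC to primed pileups was −0.13, and −0.02 at gene ends, where the quartiles were −0.39 and 0.30. Without scaling these medians were 0 and 0.11, so the first restates the scaling factor. Across regions, which are not independent replicates, the correlation of log pileups was 0.74, and 0.88 at gene ends. The hTBLC pileup was over 4 times higher at 1194 regions and the primed pileup over 4 times higher at 2172 regions. At gene ends these numbers were 19 and 100. Without scaling they were 1563 and 1532 at all shared regions and 30 and 72 at gene ends, so the surplus on the primed side at all shared regions rests on the scaling. Among regions with a pileup of at least 100 in either library, the strongest excess in primed was 12209 bp from an end of AHI1, a gene of the ciliary transition zone, on chromosome 6 at 135270842 to 135271636, with pileups of 224 in primed and 12 in hTBLC (20.4 times, 11.5 to 40.1). An intergenic region 145287 bp from the nearest gene end, that of the axon guidance receptor gene ROBO2, had 180 and 10, and one 9471 bp from ONECUT1 had 116 and 8. The strongest excess in hTBLC lay inside a gene 24260 bp from an end of WWC1 on chromosome 5 at 168447939 to 168448187, with pileups of 6 and 155 (23.6 times, 10.6 to 65.3). Regions inside genes 296856 bp from the nearest gene end, of TENM4, and 15499 bp from an end of ACSL5 followed, with 9 and 145 and with 8 and 126. These extremes were picked as the highest ratios, so their intervals understate the uncertainty of the ratios. Matched regions can also overlap only in part, so a ratio can compare neighbouring sites. Nearest to TENM4 the primed region ended at 78949810 and the hTBLC region began at 78949750. Nearest to ONECUT1 the primed region ran from 52744752 to 52746432 and the hTBLC region from 52744763 to 52745099.

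Along the chromosomes, the hTBLC-only share of library-only regions was lowest on chromosome 22 at 40.4% (38.4 to 42.4), 19 at 42.6% (40.7 to 44.5) and 17 at 43.2% (41.8 to 44.6). It was highest on chromosome 4 at 57.5% (56.6 to 58.3), followed by 13 at 54.9% and 18 at 54.8%. In 1 Mb windows with at least 30 library-only regions, the share fell with the density of protein-coding genes. It went from 62.4% (61.7 to 63.2) without a gene to 54.6% with 1 to 5 genes, 48.5% with 6 to 15 and 42.9% (42.2 to 43.6) with over 15. Single windows reached further. On chromosome 11 from 71 to 72 Mb there were 8 hTBLC-only and 43 primed-only regions, and on chromosome 14 from 71 to 72 Mb 11 and 52. On chromosome X from 27 to 28 Mb, around MAGEB10, there were 41 and 1, and from 142 to 143 Mb, around MAGEC2, 45 and 2. On chromosome 21 from 16 to 17 Mb, where no protein-coding gene lies, there were 44 and 4. Chromosome 1 from 124 to 125 Mb, in the centromeric part, had 46 and 1, in a stretch where short reads are hard to place.

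**Figure D4:**
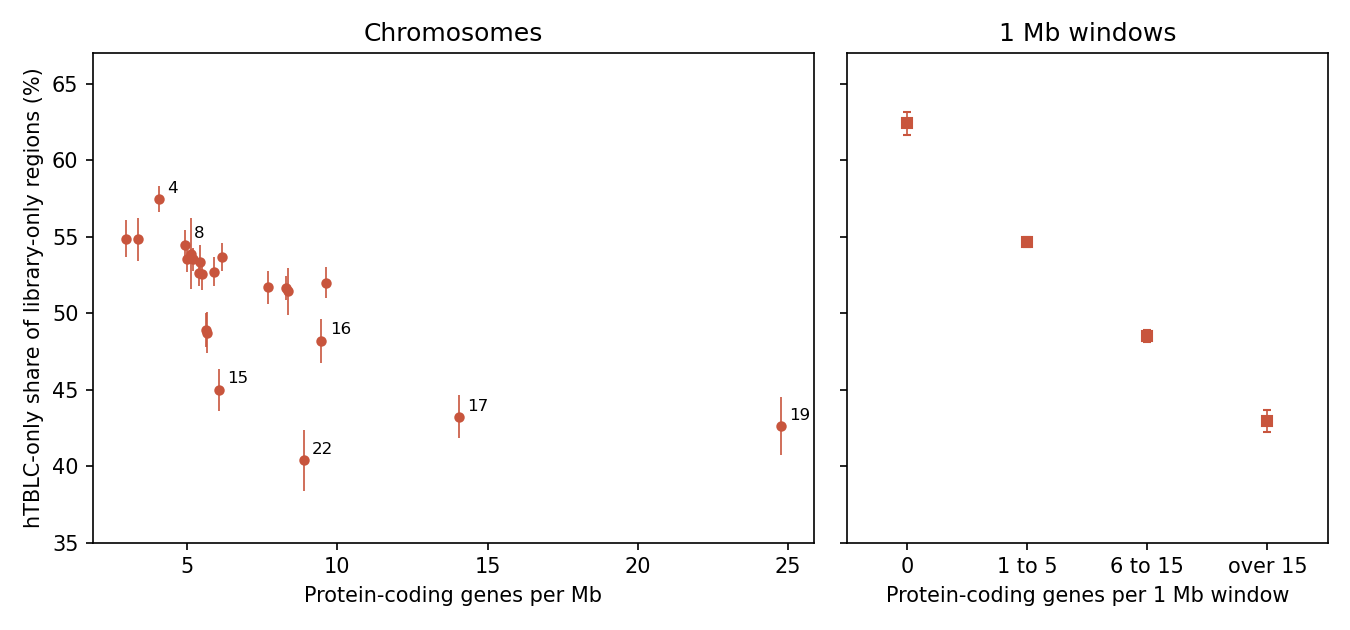
Both panels have the hTBLC-only share (%) of library-only regions on the y axis, which starts at 35%, with Wilson 95% intervals; the x axes give protein-coding genes per Mb of each chromosome and classes of 1 Mb windows by their number of protein-coding genes. Chromosome 22 at 40.4% and chromosome 4 at 57.5% are the ends of the range. The windows, each with at least 30 library-only regions, fall from 62.4% without a gene to 42.9% with over 15.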

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

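The common floor, the scaling at that floor, the stronger gene end, the removal of further lines and the contact criterion were chosen after seeing the data. No paired analysis was possible because each group has 1 library. Under every alternative that gave these values, hTBLC-only regions were more often intergenic than primed-only regions, chromosome 22 had a lower hTBLC-only share than chromosome 4, and windows without a gene had a higher hTBLC-only share than windows with over 15 genes. The primed-only share at gene ends exceeded the hTBLC-only share in each except the top 50000.

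With a −log10 q of at least 5, there were 157025 primed and 148314 hTBLC regions, 63.5% and 67.4% shared. Gene ends held 3.98% of primed-only and 3.09% of hTBLC-only regions, and intergenic positions 34.0% and 38.6%. The excess of primed-only over hTBLC-only gene ends, 78 genes in the full lists, was 291. The hTBLC-only share was 45.8% in total, 42.1% near genes, 51.1% on chromosome 4 and 35.4% on chromosome 22. With a −log10 q of at least 10, there were 100161 and 96289 regions, 65.6% and 68.2% shared, with 4.73% and 3.79% at gene ends, 34.2% and 37.8% intergenic and an excess of 222 genes. The hTBLC-only share was 47.0% in total, 42.8% near genes, 52.1% on chromosome 4 and 35.5% on chromosome 22. Fewer peaks pass these thresholds by construction. The cause of the other shifts was not tested.

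With the top 50000 regions, 66.7% and 66.8% were shared, gene ends held 6.44% of primed-only and 7.50% of hTBLC-only regions, intergenic positions 34.6% and 36.2%, and the share near genes was 46.9%. There were 1097 hTBLC-only gene ends, and the excess reversed to −223. The ZNF genes moved from below to 1.72 points above the random median, and the difference of hTBLC-only minus primed-only regions reversed at GPR176 (2), NFIB (1), GRIA2 (−2) and ST3GAL1 (−3). The cause was not tested. Among library-only regions with a −log10 q of at least 10, gene ends open in 1 library numbered 176 primed and 114 hTBLC, gene ends held 2.41% of hTBLC-only regions and intergenic positions 38.6%. The hTBLC-only share was 47.2% in total, 41.7% near genes, 54.0% on chromosome 4 and 31.3% on chromosome 22, and ST3GAL1 reversed to −1. The cause was not tested.

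With overlap of at least 50% of both regions, 50.7% and 48.9% were shared, with 5.08% and 4.25% of library-only regions at gene ends, 38.6% of hTBLC-only regions intergenic and 48.8% hTBLC-only near genes. With regions within 500 bp counted as shared, these were 68.3% and 66.3% shared, 2.81% and 2.01% at gene ends and 40.7% intergenic. Gene end windows of 500 bp gave 1.80% and 1.36% at gene ends and 34.1% and 40.3% intergenic, from narrower windows. The share near genes was 45.6% within 10 kb, where ZNF608 reversed to −2, and 50.2% within 200 kb. The cause was not tested.

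Scaling the deeper library removed 0 peaks under the planned threshold, so it says nothing about stability. At the common floor, the excess of primed-only gene ends was 34, 63.5% and 60.2% were shared, and the hTBLC-only share was 53.6% in total, 49.6% near genes and 58.9% on chromosome 4. After scaling depth at that floor, the excess was 103, 61.6% of hTBLC regions were shared and the hTBLC-only share was 51.2% in total, 47.2% near genes and 56.4% on chromosome 4. With the stronger gene end alone the excess was 120. The cause was not tested.

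Without the planned depth scaling, of 197 list shares under alternatives 182 kept their place inside or outside the central 95% of random lists; shares inside it can still change side of the random median, as for naive and neural genes. Of 1892 differences at named genes, 1114 stayed within 1.5 times, as did 233 of 342 list counts. Of 1035 gene end states, 698 stayed as they were. Motifs, base composition, the 5′ end of genes alone and windows of unequal length around the start were not run, for want of genome sequence and strand. A region at pileups near 6 or 7, the lowest called, can be missed at this depth, which limits statements on weak regions. The same limit holds for regions of low fold over their local background, as at POU5F1 (2.94), LEFTY2 (2.21) and SIX3 (1.99).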

Other observations

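The tests on leaving out 1 gene and on GC bias were chosen after the result was seen, and so were the common floor and the intervals over resampled genes or windows. On chromosome 19, gene ends at ZSCAN4, ZNF154 and ZNF671, which lie within a cluster of zinc finger genes, were open in primed alone. ZNF154 had a primed pileup of 92 (74.2 to 113) and ZNF671 one of 64 (49.3 to 81.7), with no hTBLC region. Neighbouring genes had gene end regions in both libraries, with pileups of 73 in primed and 85 in hTBLC at ZNF551, 65 and 98 at ZNF776, and 71 and 84 at ZNF211. These genes were singled out after their values were seen. Gene end regions without contact to the other library also included primed ones at WDR41, CTAGE1, SLC30A4-AS1 and FUT8 and hTBLC ones at PRR5L, IL37, CXCL17, GBP1, KIF2B and LOC128966567. The pileups at IL37, CXCL17 and GBP1 were 33, 55 and 29. Ranks without a line leave each single gene uncertain.

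The hTBLC-only share fell with gene density. Gain or loss of whole chromosomes is argued against as the cause of the trend within chromosomes. The Spearman rho between genes and share over 1 Mb windows was negative within 23 of 23 chromosomes, with a median of −0.43. On chromosome 22, which had the lowest share, it was only −0.06. These correlations do not address differences between whole chromosomes. Calling thresholds and depth are argued against as the whole cause. The difference between windows without a gene and with over 15 was 19.5 points. It was 14.6 with a −log10 q of at least 5 in both lists and 18.8 (17.2 to 20.4) at a common floor after scaling depth. These values used windows with at least 30 library-only regions. Among library-only regions with a −log10 q of at least 10 the difference was 24.9 (21.3 to 28.7). That value used windows with at least 5 such regions, so its size cannot be set against the others. GC bias between the libraries cannot be told apart from the state, because GC content was not measured. Shared regions at gene ends had a median log2 ratio 0.11 above intergenic ones. Outside gene ends, shared regions had their lowest medians on chromosomes 22 (−0.32), 17 (−0.28), 15 (−0.27), 16 (−0.26) and 19 (−0.24). Over all shared regions the median was −0.13. These chromosomes also had the lowest hTBLC-only shares. Opening of gene-poor chromatin in hTBLCs may also account for the trend, a hypothesis that 1 library per state leaves untested.

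Olfactory receptor genes had more hTBLC-only regions than random lists. A shift of whole 1 Mb windows is argued against. Other genes in the same windows had 48.4% hTBLC-only (46.2 to 50.7), against 58.3% (53.6 to 62.8) for the receptor genes. Each region went to its nearest gene, so a shift confined to the receptor clusters is not addressed. A few 1 Mb windows are argued against by resampling 44 windows, where the lower bound of the share was 52.6% against 48.0% for all genes. Since 1 cluster of receptor genes can span neighbouring windows, this cannot settle whether a few clusters carry the pattern. Weak calls are argued against as the whole cause, since the share was 75% (62.3 to 86.6) among regions with a −log10 q of at least 10, with 42 hTBLC-only and 14 primed-only regions, against 41.7% for all genes, though with the top 50000 regions of each list it was 53.9%, at percentile 91.2. Reads shared between related genes, GC bias between the libraries and a change of chromatin state may each account for the pattern and were not tested.

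Core pluripotency genes had more primed-only regions. Weak calls are argued against only narrowly, since among regions with a −log10 q of at least 10 the share was 20% (0 to 41.6), a range that ends just below the 41.7% of all genes; the list then lay at percentile 2.8, inside the central 95% of random lists, and at 23.4 with the top 50000 regions. Unequal calling thresholds and depth are argued against by a share of 33.9% (21.5 to 44.1) at a common floor after scaling depth, against 47.2% for all genes. Whether 1 gene of the list carries the pattern stays open, since without TERF1 the list lay at percentile 8.15 of random lists. With 4 of 19 lists outside the central range and 1 library per state, reduced accessibility around these genes in hTBLCs may be real or may be a difference between these libraries.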
